A study of Mus musculus with 24 samples.

How the data were processed

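The series holds 24 bulk RNA sequencing libraries from male C57BL/6 mice 11 weeks old. Mice received propyzamide, a herbicide that blocks plant microtubules, or an empty vehicle. Libraries were taken without stimulation, 3 h after anti-CD3 and 24 h after anti-CD3, an antibody that triggers the T cell receptor complex. This gives 6 groups of 4 libraries. The series title places the work in T cells of an inflammatory bowel disease model, while the tissue, any cell sort, the doses and the protocols of treatment are not given in the sources used here. Replicates carry no number in the labels and were numbered in the order of their records, so no pairing was assumed. The library names hold an i5 index: ACTCTAGG for both unstimulated groups and vehicle at 3 h, and TCTTACGC for the other 3 groups. The labels do not say whether the index marks a batch.

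Libraries were made by the SMART-seq2 protocol, and per the submitters' processing notes they were quantified with kallisto on GRCm38 without a version being stated. The deposited files give expected counts (estimated counts per transcript, not scaled to depth) for 142604 transcripts, per the file headers. The deposited files also give TPM, per the file headers. A further column that the authors deposited, of the unit class other, is the effective transcript length in bases. Expected counts were summed over transcripts to 55401 genes and rounded. Gene names came from the files, and coordinates from the GENCODE annotation of GRCm38.

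Total counts per library ran from 438750 to 2.07e+06 in 23 libraries, and propyzamide 24 h replicate 3 had 9812500. Counts in named protein-coding genes ran from 18119 to 161440 in those 23 libraries and reached 2944600 in the deepest. A group of 12 gene models related to Gm10800 by shared sequence took most counts. Models were placed in it when at least 5% of their stretches of 31 bases occur in Gm10800, a rule set after the data were seen. A gene with no counts in a group is given a floor of 3 counts over that group. Intervals have 95% confidence, and intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

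Counts were tested with edgeR 4.0.16 in R 4.3.3. The design had 1 coefficient per group over all 24 libraries, with filterByExpr, TMM normalization and the quasi-likelihood F test. The filter left 3799 genes, of which 2468 are named protein-coding genes and 1331 others. Named protein-coding genes leave out models known by a number or clone, olfactory and vomeronasal receptors and mitochondrial genes, a grouping made after the data were seen. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 or less within a comparison. Levels are TMM-normalized CPM, as mean ± SD of 4 libraries, and log2 fold changes carry their standard error. The 11 comparisons were propyzamide against vehicle at each stage and over the mean of the 3 stages, anti-CD3 at 3 h and at 24 h against unstimulated within each treatment, 24 h against 3 h with vehicle, and the interaction of treatment and anti-CD3 at each time. P-values from these replicates measure the spread between these samples only.

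Before the data were examined, 34 gene lists were fixed, 30 written out by gene and 4 defined by gene name prefix. Of these, 27 had at least 3 measured genes and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then again with an estimated correlation and with fry. Camera compares a list with all other tested genes, named or not, so a shift between named and other genes can add to its calls. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. Their names stand with their results. Groups, comparisons, tests, the lists and the rule for named genes were all fixed before the data were examined. That rule takes protein-coding genes with an adjusted p of 0.05 or less, an absolute log2 fold change of at least 1 and a mean log2 level of at least 3, and names the 8 higher and 8 lower genes with the smallest p. Where none passes it takes the 5 genes with the smallest p. It adds up to 4 members of each list with the smallest p and, for propyzamide, a panel of receptor, cytokine and T cell genes. Some genes that this rule takes are not reported here.

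Other settings chosen before the data were examined were RLE normalization, no filter on low counts, a transcript length offset, a fit of only the groups compared, DESeq2 1.42.0, limma-voom with sample quality weights, limma-trend on log2(TPM + 1), and leaving out each library in turn in 24 fits. The fits that left out a library repeated the filter, which then kept 3893 to 4623 genes against 3799 with all libraries. A call lost there can come from the changed set of genes as well as from the library. A mean over the unstimulated and 24 h stages was set in advance for the treatment comparison. After the data were seen, 3 more settings were added: named protein-coding genes only, without 2 outlying libraries (propyzamide 24 h replicate 3 and propyzamide 3 h replicate 3), and both together. Splits of the libraries into other groups of the same sizes were fitted the same way, all 35 for a comparison of 4 with 4 and 100 drawn ones otherwise. Library measures were compared with 2-sided exact permutation tests in scipy 1.17.1 under Python 3.11.15, 48 tests in all, where the smallest p that 4 against 4 allows is 0.0286. List scores are means of log2 CPM over named protein-coding genes with a pseudocount of 10.

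The edgeR test was tried on simulated data with 200 changed genes in each of 5 draws, and camera with the preset correlation was tried on lists. The estimated correlation, fry, the other tools and the permutation tests were not simulated. Genes were drawn independently of each other, with means pooled over all libraries. Of the changed genes that the filter kept in the simulated counts, comparisons of 2 groups found 4.14% to 8.74% at 2-fold. At 4-fold they found 46.7% to 60.8% and at 8-fold 82.2% to 86.8%. Changed genes that the filter dropped are not in these shares, so the shares over all changed genes are lower. For the mean over stages these shares were 49.3%, 96.5% and 99.6%. The interactions found 1.06% to 1.76% at 2-fold, 13.4% to 16.6% at 4-fold and 49.0% to 49.8% at 8-fold. Between 2.53% and 5.95% of the calls were genes left unchanged in the simulation. Lists were taken at random from genes that varied independently, so these draws do not show how camera does on genes that vary together. A list of 20 genes raised 2-fold was found in 5 of 5 draws in each comparison. A list of 20 unchanged genes had p under 0.05 in 1 of 5 draws for propyzamide at 24 h, for anti-CD3 at 24 h with propyzamide and for both interactions, and in 0 of 5 for the other 7 comparisons. No pair of replicates was identical, and in 36 pairs each differed beyond counting error.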

Results

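The libraries held RNA of several cell types, with transcripts of several other types above those of T cells. As CPM over named protein-coding genes, the mean over 24 libraries was 888.5 for the T cell core genes, which encode the T cell receptor complex and its signalling partners. It was 8873 for intestinal epithelium genes, 3687 for B cell genes, 8487 for plasma cell genes, 1411 for macrophage and monocyte genes and 11900 for dendritic cell genes, of which H2-Aa, H2-Ab1, H2-Eb1 and Cd74 are also expressed by B cells. Cd3e, a chain of the T cell receptor complex, had 365 counts over all 24 libraries, 52 of them outside the deepest. Fabp1, a fatty acid binding protein of enterocytes, had 4450 and 856.

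Most counts lay in the 12 models related to Gm10800, called satellite-like here, and not in known genes. Gm10800 (GRCm38 chromosome 2, 98666547 to 98667301, minus strand) took a mean of 44.3% of the estimated counts, and its neighbour Gm10801 took 8.01%. In 9 of the 12 models of this group the sequence matches itself best at the repeat length of the mouse major satellite. The group took 72.2% to 86.8% of the counts in 23 libraries and 40.2% in propyzamide 24 h replicate 3. Its mean share was 75.2% ± 2.74 in vehicle unstimulated libraries, 80.2% ± 3.85 at 3 h and 83.5% ± 2.47 at 24 h (SD, n = 4, exact permutation p = 0.0286 for 24 h against unstimulated, adjusted 0.305). With propyzamide it was 77.3% ± 2.97, 76.8% ± 3.27 and 70.3% ± 20.1, the last with a median of 79.5%. Named protein-coding genes held 3.77% to 9.67% of the counts in the 23 libraries, or 18119 to 161440 counts, and 30.01% in the deepest. Between 10761 and 25037 genes were detected per library, against 42974 in the deepest. Biological variation between replicates was 46.4% (edgeR common dispersion 0.215).

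**Figure D1:**
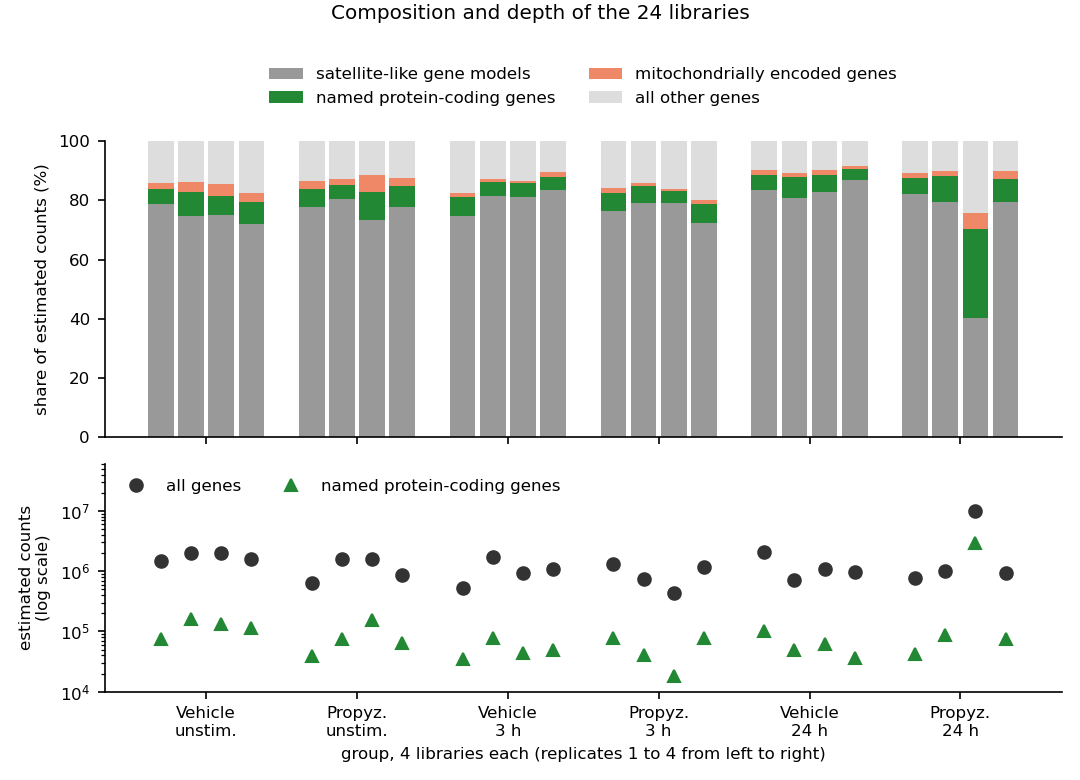
The upper panel stacks, for each of the 24 libraries by group, the percent of estimated counts in satellite-like models, named protein-coding genes, mitochondrial genes and all others; the lower panel gives total and named protein-coding counts as points on a log axis. Satellite-like models take 72.2% to 86.8% in 23 libraries and 40.2% in propyzamide 24 h replicate 3, which also has the highest total, 9812500 counts.

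Gbp2, Gzmb, Acod1, S100a9 and Serpina3g rose 3 h after anti-CD3 with vehicle. Gbp2, an interferon-inducible guanylate-binding GTPase (ENSMUSG00000028270.12, chromosome 3, 142620602 to 142638008, plus strand), rose from 0.887 ± 0.651 to 29.7 ± 28.4 CPM (log2 fold change 4.88 ± 0.84, edgeR adjusted p = 0.00442). Gzmb, the cytotoxic protease granzyme B (chromosome 14, 56258838 to 56262260), rose from 0.65 ± 0.53 to 17.2 ± 13.7 (4.50 ± 0.83, adjusted p = 0.00665). Acod1, the itaconate-forming enzyme of activated macrophages (chromosome 14, 103046977 to 103056573), rose from 0.785 ± 1.25 to 30.6 ± 19.0 (4.97 ± 0.93, adjusted p = 0.00665). In a vehicle unstimulated library 3 counts are 1.48 to 2.04 CPM of its total, without TMM scaling. The unstimulated means of Gbp2, Gzmb and Acod1 lie below this, so the size of their rises rests on few counts. S100a9, a calprotectin subunit of neutrophils and monocytes, went from 0 to 47 counts, at least 32.8-fold higher, with 13.1 ± 10.3 CPM at 3 h (adjusted p = 0.00442). Serpina3g, a protease inhibitor of activated leukocytes, rose by 3.49 ± 0.78 (adjusted p = 0.0373).

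In the same comparison edgeR called 4 genes lower, 3 of them made by Paneth cells, while the intestinal epithelium list did not pass (4 of 16 positive, median -0.49, adjusted p = 0.22). Itln1, a glycan-binding lectin of Paneth and goblet cells (chromosome 1, 171518122 to 171535294), fell from 225 ± 37.1 to 56.5 ± 8.77 CPM (-1.99 ± 0.42, adjusted p = 0.0297). Defa23 and Defa39, Paneth cell antimicrobial peptides, changed by -2.08 ± 0.46 (adjusted p = 0.0373) and -1.996 ± 0.45 (adjusted p = 0.0375). Selenop, a selenium carrier, fell from 47.3 ± 16.7 to 8.69 ± 6.32 CPM. Alpha-defensin genes are close paralogs and share reads, so single members are uncertain. Cxcl10, an interferon-induced chemokine, had 35 counts at 3 h against 1 (ratio 73.2, counting interval 12.3 to 2970). Ccl24, an eosinophil chemokine chosen after its values were seen, had 60 against 1 (ratio 125, 21.7 to 5040).

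Of the gene lists, 3 rose and 4 fell at 3 h with vehicle, where named protein-coding genes had a median of -0.17 and the other tested genes 0.09. The 16 mitochondrially encoded genes were all lower (median -1.18, adjusted p = 2.38e-14), with 11 fallen when adjusted over the list alone and none when adjusted over all genes. mt-Co1 was at -1.32 ± 0.32 (adjusted p = 0.08), and the mitochondrial share of counts was 1.14% ± 0.336 against 3.19% ± 0.855 unstimulated (exact permutation p = 0.0286, adjusted 0.305). Interferon response genes rose (8 of 9 positive, median 0.99, adjusted p = 2.85e-05), with 1 risen over all genes, 2 adjusted over the list alone, and Irf1, an interferon regulatory factor, at 1.51 ± 0.48 (adjusted p = 0.317). Granulocyte and mast cell genes rose (4 of 4 positive, median 3.73, or 2.22 with S100a9 and S100a8 at their bounds, adjusted p = 5.91e-05). T helper 1 genes rose too (3 of 3 positive, median 1.82, adjusted p = 0.0138). Adjusted over the list alone, 2 granulocyte genes and 0 T helper 1 genes had risen. Plasma cell genes fell (0 of 7 positive, median -1.27, adjusted p = 5.91e-05, 2 adjusted over the list alone), as did immunoglobulin variable segments (0 of 8, -1.27, adjusted p = 0.00173) and B cell genes (1 of 11, -0.62, adjusted p = 0.029), neither with a member passing adjusted over the list alone. With an estimated correlation none of these 7 lists passed: adjusted p = 0.112 for mitochondrial, interferon, granulocyte, plasma cell and T helper 1 genes, adjusted p = 0.141 for variable segments, and adjusted p = 0.71 for B cell genes. The granulocyte call ended without vehicle unstimulated replicate 3 (median 0.18) or vehicle 3 h replicate 4 (-0.25), fits in which that list had 5 measured genes and not 4. Without the filter on low counts the T helper 1, granulocyte and variable segment calls ended (-0.04, -0.06 and -0.67). The B cell call ended with named protein-coding genes only (-0.35) and without any 1 of vehicle unstimulated replicates 2 (-0.29) and 4 (-0.40) and vehicle 3 h replicates 1 (-0.71), 2 (-0.50), 3 (-0.54) and 4 (-0.53).

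In all, edgeR called 11 genes at 3 h with vehicle, 7 higher and 4 lower, against 237 at an unadjusted p under 0.05. RLE normalization gave 7 higher and 7 lower, named protein-coding genes only gave 15 and 6, DESeq2 gave 15 and 19, and the fit without 2 outlying libraries gave 11 and 20, each keeping all 11. In 3 settings fewer were kept and most called genes were lower: limma-voom gave 1 higher and 17 lower and limma-trend 1 and 6, each keeping 4 of the 11, and a fit of only the groups compared gave 2 and 24, keeping the 5 it tested. The length offset gave 6 and 3, keeping 8, and no filter on low counts gave 21 and 36, keeping all 11. Leaving out vehicle unstimulated replicates 1, 2, 3 and 4 in turn gave 5, 4, 6 and 6 called genes, and vehicle 3 h replicates 1, 2, 3 and 4 gave 5, 6, 10 and 5. All were higher except 1 gene each without vehicle unstimulated replicate 3 and vehicle 3 h replicate 4, so the lower calls were mostly lost. These fits tested 4471 to 4604 genes against 3799 with all libraries, which can also cost calls. Gbp2, S100a9 and Acod1 were called in all 8 of these fits, Gzmb in all but that without vehicle unstimulated replicate 2, Ccl24 in all but that without vehicle 3 h replicate 4, Serpina3g, Selenop and Cxcl10 in 2, and Itln1, Defa23 and Defa39 in none.

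With vehicle, 24 h after anti-CD3, interferon-inducible genes rose. Ifi27l2a, an interferon-inducible gene (ENSMUSG00000079017.3, chromosome 12, 103442167 to 103443680, minus strand), rose from 3.05 ± 2.46 to 40.4 ± 8.09 CPM (3.64 ± 0.61, adjusted p = 0.0049). Gbp2 reached 28.0 ± 20.8 (4.85 ± 0.84, adjusted p = 0.0049). Tap1, a peptide transporter for MHC class I, rose from 2.97 ± 2.06 to 23.4 ± 6.58. Ly6a and Ifitm3, both interferon-induced membrane proteins, rose by 2.89 ± 0.62 and 2.495 ± 0.57, and these 3 genes shared an adjusted p of 0.0417. Gzmb rose by 4.14 ± 0.84 (adjusted p = 0.0264), and S100a9 had 33 counts against 0, at least 22.1-fold higher (adjusted p = 0.0204).

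Olfm4, Elf3 and Jchain fell over the same 24 h. Olfm4, a marker of intestinal crypt base cells (chromosome 14, 79984081 to 80023139), fell from 71.7 ± 29.5 to 8.46 ± 3.12 CPM (-3.09 ± 0.64, adjusted p = 0.0319). Elf3, an epithelial transcription factor, fell from 15.8 ± 2.95 to 1.34 ± 0.972 (-3.46 ± 0.77). Jchain, the joining chain of secreted IgA and IgM, fell from 94.9 ± 17.4 to 15.5 ± 5.07 (both adjusted p = 0.0417). Lag3, a co-inhibitory receptor of activated T cells, rose by 3.03 ± 0.67, and Bst2, an interferon-induced antiviral protein, by 3.38 ± 0.78. Cxcl10 had 37 counts against 1 (ratio 74.2, 12.5 to 3010), and Acod1, chosen here after its values were seen, rose by 3.97 ± 0.94 (adjusted p = 0.0481).

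**Figure D2:**
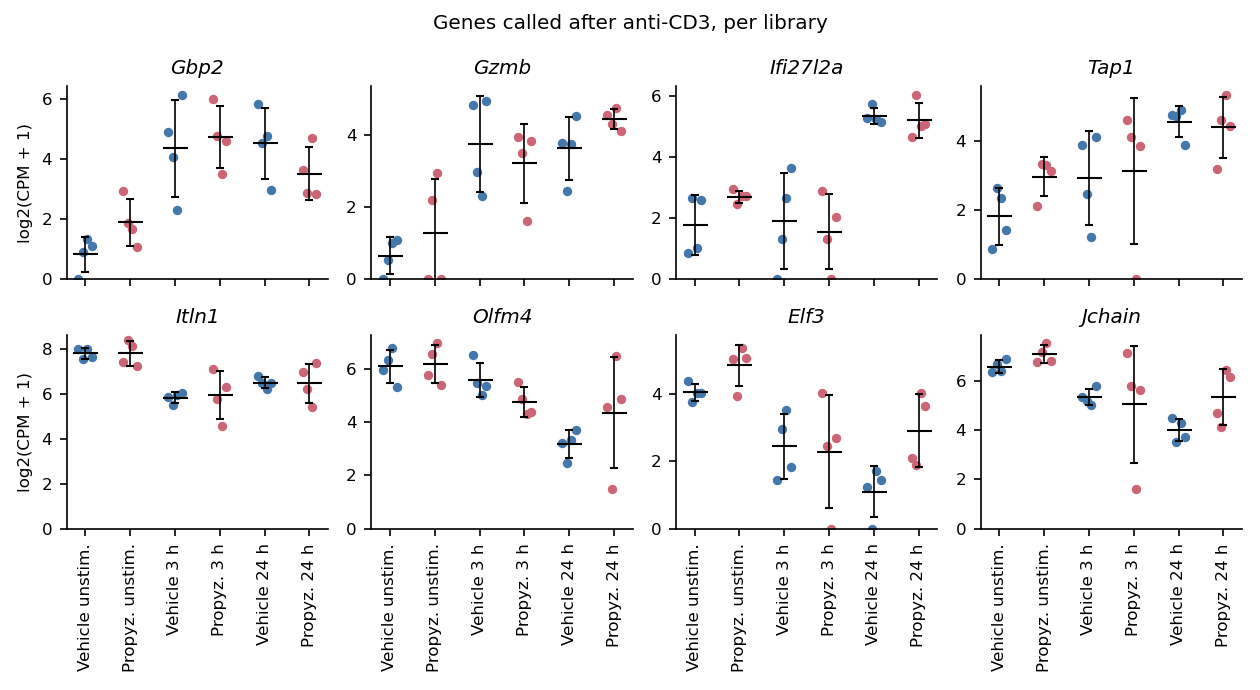
Each panel gives log2(CPM + 1) of 1 gene (Gbp2, Gzmb, Ifi27l2a, Tap1, Itln1, Olfm4, Elf3, Jchain) for the 4 libraries of each of the 6 groups, as points with mean and SD bars. With vehicle, mean Ifi27l2a is 3.05 CPM unstimulated, 4.53 at 3 h and 40.4 at 24 h, while mean Olfm4 is 71.7, 51.3 and 8.46.

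Interferon response was the list whose rise held under every list test run. All 9 measured members were higher at 24 h (median 1.57, adjusted p = 1.04e-13, and adjusted p = 0.0127 with an estimated correlation), with 3 risen over all genes and 6 adjusted over the list alone. Intestinal epithelium genes fell (1 of 16 positive, median -2.91, or -2.76 with Phgr1 and Apoa4 at their bounds, adjusted p = 1.16e-17). Of these 16, 1 fell over all genes and 15 adjusted over the list alone, and adjusted p = 0.0627 with an estimated correlation. Lgals4, an epithelial galectin, was at -4.09 ± 1.01 (adjusted p = 0.064). Plasma cell genes (2 of 7 positive, median -0.97, adjusted p = 8.15e-04, 2 fallen adjusted over the list alone) and immunoglobulin variable segments (0 of 8, -1.76, adjusted p = 8.03e-04) fell, both with adjusted p = 0.121 with an estimated correlation. Mitochondrially encoded genes fell (1 of 16, -0.68, adjusted p = 9.58e-05, 1 adjusted over the list alone, and adjusted p = 0.37 with an estimated correlation).

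Lymphocyte lists rose at 24 h with vehicle, where named protein-coding genes had a median of 0.11 and the other tested genes -0.24. Naive and memory T cell genes were all higher (5 of 5, median 1.07, adjusted p = 3.58e-04, 1 adjusted over the list alone, and adjusted p = 0.076 with an estimated correlation). T cell core genes rose (5 of 5, 1.11, adjusted p = 0.00632, and adjusted p = 0.121 with an estimated correlation). Ribosomal protein genes (72 of 79, 0.70, adjusted p = 2.05e-14), heat shock and dissociation genes (8 of 8, 0.75, adjusted p = 0.00121), B cell genes (10 of 11, 0.61, adjusted p = 0.00459) and NF-kappaB targets (8 of 10, 0.63, adjusted p = 0.0393) rose, with 1 NF-kappaB target and no other member passing adjusted over the list alone. For these 4 the estimated correlation gave adjusted p = 0.359, adjusted p = 0.333, adjusted p = 0.41 and adjusted p = 0.41. With named protein-coding genes only, the T cell core, B cell, plasma cell and NF-kappaB calls ended, with medians of 0.11, 0.44, -0.62 and 0.34, and without the filter on low counts the mitochondrial (-0.38), variable segment (-0.28) and NF-kappaB calls (0.27) ended. RLE normalization also ended the NF-kappaB call (0.72). The B cell call also ended without vehicle unstimulated replicate 1 (0.45) and without vehicle 24 h replicate 2 (0.35).

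At 24 h with vehicle edgeR called 16 genes, 12 higher and 4 lower, against 272 at an unadjusted p under 0.05. RLE normalization gave 5 higher and 0 lower, named protein-coding genes only gave 17 and 17, DESeq2 gave 24 and 10, and limma-trend on TPM called 0. Limma-voom gave 15 and 6, keeping 9 of the 16, and the length offset gave 7 and 4, keeping 11. In other settings most called genes were lower: 17 higher and 34 lower in a fit of only the groups compared, 20 and 23 without 2 outlying libraries, 26 and 51 with named protein-coding genes only and without these libraries, and 18 and 46 without the filter on low counts. Leaving out vehicle unstimulated replicates 1, 2, 3 and 4 in turn gave 4, 1, 2 and 3 called genes, and vehicle 24 h replicates 1, 2, 3 and 4 gave 2, 4, 3 and 9. Lower among these were 1 gene each without vehicle unstimulated replicates 1 and 4 and 2 without vehicle 24 h replicate 4. Here too more genes were tested, 4526 to 4623 against 3799 with all libraries, which can cost calls. Ifi27l2a was called in all 8 fits, Gbp2 in all but that without vehicle unstimulated replicate 2, and Elf3, Jchain, Lag3, Bst2, Ifitm3, Cxcl10 and Acod1, in none; Gzmb, Ly6a and Tap1 were called in 1, Olfm4 in 3 and S100a9 in 4. The 2 groups carry different i5 indexes, so for single genes index and group cannot be told apart in this comparison, nor in 24 h against 3 h with vehicle or in the anti-CD3 comparisons with propyzamide. For the interferon and epithelial lists, the 3 h groups, which differ in index and in treatment, differed by 0.0405 and -0.11.

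**Figure D3:**
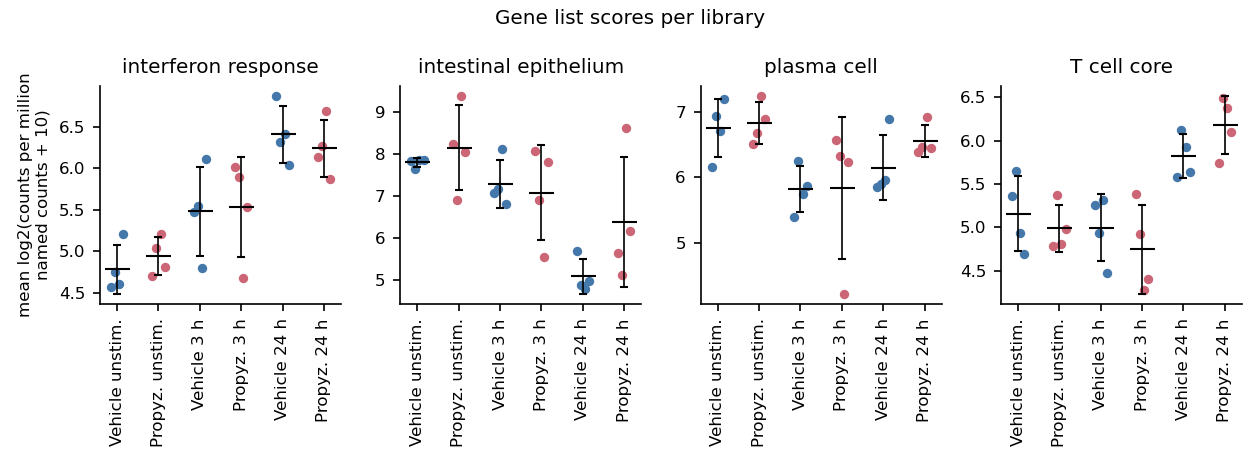
Each panel gives 1 list score per library, the mean log2 of CPM over named protein-coding genes plus 10, for the interferon response, intestinal epithelium, plasma cell and T cell core lists over the 6 groups, as points with mean and SD bars. Interferon scores of the 8 unstimulated libraries lie between 4.57 and 5.2, and propyzamide 24 h replicate 3 scores 6.69 for interferon and 8.61 for epithelium.

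Between 3 h and 24 h with vehicle no single gene passed, while lymphocyte lists rose and the epithelial list fell. The median log2 fold change was 0.27 over named protein-coding genes and -0.32 over the other tested genes, so a rise of a list can hold this shift. The genes with the smallest p were Ifi27l2a (3.15 ± 0.63), Shisa5, an endoplasmic reticulum protein of the p53 response (2.38 ± 0.49, both adjusted p = 0.0595), Itm2b, H2-T23, a non-classical MHC class I gene, and Tcp11l2. B cell genes rose (10 of 11, median 1.31, adjusted p = 2.47e-05, 5 risen adjusted over the list alone), with Ighd, the IgD heavy chain, at 2.17 ± 0.55 (adjusted p = 0.106). Naive and memory T cell genes (5 of 5, 1.77, adjusted p = 5.18e-04, 3 adjusted over the list alone) and T cell core genes (4 of 5, 1.68, adjusted p = 0.00707, 2 adjusted over the list alone) rose, with S1pr1, the receptor for lymphocyte egress, at 2.34 ± 0.70 (adjusted p = 0.156). Ribosomal proteins (73 of 79, 0.97, adjusted p = 8.98e-14), heat shock (7 of 8, 1.60, adjusted p = 3.41e-04, 4 adjusted over the list alone) and mitochondrially encoded genes (15 of 16, 0.53, adjusted p = 0.0224) rose. Tubulin and microtubule (7 of 9, 1.22), interferon response (7 of 9, 0.45), dendritic cell (4 of 4, 1.01) and glycolysis genes (9 of 10, 0.70) rose with a shared adjusted p of 0.0208, and of these 3 interferon response genes and 1 tubulin gene passed adjusted over the list alone. Intestinal epithelium genes fell (1 of 16, -2.59, or -2.37 with Phgr1 and Apoa4 at their bounds, adjusted p = 1.74e-10, 8 fallen adjusted over the list alone). With an estimated correlation none of the 11 passed, from adjusted p = 0.223 for epithelium and both T cell lists to adjusted p = 0.669 for mitochondrial genes. edgeR called 0 genes, with 462 at an unadjusted p under 0.05, against 79 by DESeq2, 6 by limma-voom, 0 by limma-trend, 15 with named protein-coding genes only and 40 without 2 outlying libraries. With named protein-coding genes only, T cell core (0.70), tubulin (0.93), glycolysis (0.42) and dendritic cell genes (0.75) lost their calls, as did glycolysis (0.37) and dendritic cell genes (0.47) without the filter on low counts and glycolysis with the length offset (0.37). Single libraries ended 3 list calls: interferon without vehicle 3 h replicates 2 (0.33) or 3 (0.24) or vehicle 24 h replicates 1 (0.18) or 2 (0.33), glycolysis without vehicle 3 h replicates 1 (0.64), 2 (0.41) or 3 (0.48) or vehicle 24 h replicate 3 (0.62), and mitochondrial genes without vehicle 3 h replicates 1 (0.44) or 3 (0.35) or vehicle 24 h replicate 1 (0.25).

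With propyzamide, 3 h of anti-CD3 raised S100a9, Serpina3g, Gbp2 and Sprr2a2. S100a9 had 75 counts against 0, at least 29.9-fold higher, and Serpina3g rose from 2.04 ± 1.88 to 48.1 ± 29.99 CPM (4.36 ± 0.81), both with an adjusted p of 0.0159. Gbp2 rose by 3.46 ± 0.79 (adjusted p = 0.0323) and Sprr2a2, a small proline-rich protein of epithelia, by 3.08 ± 0.75 (adjusted p = 0.0476). Lyz1, the Paneth cell lysozyme, fell from 582 ± 228 to 133 ± 79.1 CPM (-2.12 ± 0.41, adjusted p = 0.0159). Mptx2, a mucosal pentraxin of Paneth cells, changed by -4.01 ± 0.87 (adjusted p = 0.029), Defa29 by -2.60 ± 0.54, and Cd81, a tetraspanin of lymphocytes and other cells, by -2.28 ± 0.48 (both adjusted p = 0.0227). Gapdh, a glycolytic enzyme, fell from 63.3 ± 40.8 to 8.81 ± 8.05 (-2.78 ± 0.63, adjusted p = 0.0323). The mitochondrial genes mt-Nd5, mt-Nd4 and mt-Cytb changed by -1.58 ± 0.32, -1.54 ± 0.31 and -1.55 ± 0.34.

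Among lists at 3 h with propyzamide, 2 rose and 10 fell. Named protein-coding genes had a median log2 fold change of -0.42 in this comparison and the other tested genes 0.29. The fall of a list can hold this shift as well as a change of its own. Granulocyte genes rose (4 of 4, median 2.95, also with S100a9 at its bound, adjusted p = 0.00274, 2 risen adjusted over the list alone), as did interferon response genes (7 of 9, 0.66, adjusted p = 0.00475, 2 risen adjusted over the list alone). Mitochondrially encoded genes fell (0 of 16, -1.35, adjusted p = 3.31e-14, 5 fallen over all genes and 13 adjusted over the list alone), with ribosomal proteins (7 of 79, -0.55, adjusted p = 1.92e-06) and glycolysis genes (1 of 10, -0.99, adjusted p = 2.98e-04, 3 adjusted over the list alone). Intestinal epithelium (1 of 16, -1.56, adjusted p = 0.00115), plasma cell (0 of 7, -1.14, adjusted p = 0.00317) and B cell genes (0 of 11, -0.91, adjusted p = 0.00784) fell. Immediate early and T cell receptor response genes (2 of 12, -0.83), tubulin and microtubule genes (0 of 9, -1.13) and immunoglobulin variable segments (2 of 8, -1.22) fell with a shared adjusted p of 0.0154, and glucocorticoid response genes (0 of 6, -0.77) with adjusted p = 0.0166. Adjusted over the list alone, 3 variable segments and 1 gene each of the epithelial, plasma cell, tubulin and glucocorticoid lists passed, and no ribosomal, B cell or immediate early gene. Tubb5, a beta-tubulin, was at -1.42 ± 0.45 (adjusted p = 0.153). With an estimated correlation none of the 12 passed, from adjusted p = 0.376 for 8 of them, tubulin included, to adjusted p = 0.521 for ribosomal, B cell and immediate early genes. The ribosomal (-0.20) and B cell calls (-0.61) ended without propyzamide 3 h replicate 3, the library with the fewest named counts. Without both outlying libraries the ribosomal, immediate early, tubulin, glucocorticoid, B cell and variable segment calls ended (-0.24, -0.52, -0.89, -0.60, -0.60 and -0.81). With named protein-coding genes only the immediate early (-0.60), tubulin (-0.90), B cell (-0.56) and plasma cell calls (-0.76) ended, with the length offset the glucocorticoid call (-0.90) and without the filter on low counts the granulocyte call (0.29). B cell genes also lost the call without propyzamide unstimulated replicate 4 (-0.70). Granulocyte genes lost it without propyzamide unstimulated replicate 2 (1.16) or 3 (1.60) or propyzamide 3 h replicate 1 (1.21).

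In this comparison edgeR called 27 genes, 6 higher and 21 lower, against 508 at an unadjusted p under 0.05. RLE normalization gave 6 higher and 47 lower, named protein-coding genes only gave 8 and 7, DESeq2 gave 8 and 70, and a fit of only the groups compared called 0. Limma-voom gave 0 and 7, limma-trend 1 and 4, the length offset 3 and 10, the fit without 2 outlying libraries 6 and 14, and no filter on low counts 20 and 45. Leaving out propyzamide unstimulated replicates 1, 2, 3 and 4 gave 11, 5, 0 and 11 called genes, and propyzamide 3 h replicates 1, 2, 3 and 4 gave 33, 9, 5 and 3. Of these, 7, 2, 0 and 8 were lower, then 29, 5, 0 and 0, so without propyzamide 3 h replicate 3 or 4 no gene was called lower. Over named protein-coding genes with at least 10 counts in a pair of libraries, replicate 3 had rank correlations of -0.02 to 0.06 with the other 3 libraries of its group, which had 0.34 to 0.38 with each other. S100a9, Serpina3g and Ccl24 were called in all but the fit without propyzamide unstimulated replicate 3, and each of the other 24 genes in at most 4 of the 8 fits.

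At 24 h with propyzamide, Lag3 rose from 1.15 ± 0.82 to 14.8 ± 1.89 CPM (3.65 ± 0.71, adjusted p = 0.0302). Its unstimulated mean lies below 3 counts in a library of that group, 1.89 to 4.76 CPM of the total without TMM scaling. Pml, the organizer of nuclear bodies and itself interferon-inducible (chromosome 9, 58218076 to 58249786), rose from 2.35 ± 0.826 to 18.8 ± 11.5 (3.03 ± 0.62, adjusted p = 0.0385). Zg16, a goblet cell lectin (chromosome 7, 127050156 to 127087328), fell from 38.5 ± 21.2 to 1.74 ± 2.45 (-4.37 ± 0.84, adjusted p = 0.0302). Interferon response genes rose (9 of 9, median 1.54, adjusted p = 6.09e-08, 8 adjusted over the list alone), with adjusted p = 0.0757 with an estimated correlation. Naive and memory T cell genes rose (5 of 5, 1.99, adjusted p = 6.75e-06, 5 adjusted over the list alone), with adjusted p = 0.0586 with an estimated correlation. Intestinal epithelium genes fell (0 of 16, -1.10, adjusted p = 5.16e-07, 2 adjusted over the list alone), with adjusted p = 0.229 with an estimated correlation and a median of -2.98 without both outlying libraries.

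Other lists that rose at 24 h with propyzamide were ribosomal proteins (77 of 79, median 0.68), heat shock (8 of 8, 1.37), B cell (10 of 11, 1.13), T cell core (5 of 5, 1.74), cell cycle (9 of 11, 0.93), granulocyte (3 of 4, 2.54, or 2.44 with S100a9 at its bound), regulatory T cell and co-inhibition (2 of 3, 0.58), glycolysis (10 of 10, 0.49) and NF-kappaB targets (9 of 10, 0.69). Adjusted over the list alone, 5 heat shock, 3 B cell, 3 T cell core and 3 granulocyte genes and 1 regulatory T cell gene passed. Their adjusted p as lists ran from 2.01e-10 for ribosomal proteins to 0.0496 for glycolysis and NF-kappaB targets. Mitochondrially encoded genes (0 of 16, -0.61, adjusted p = 0.00114) and variable segments (2 of 8, -0.77, adjusted p = 0.048) fell. The median over all named protein-coding genes was 0.27 and over the other tested genes -0.42, a shift that these list calls can hold too. With an estimated correlation none of these 11 passed, from adjusted p = 0.123 for T cell core to adjusted p = 0.517 for glycolysis. With named protein-coding genes only T cell core (0.78), regulatory (0.27), cell cycle (0.57), granulocyte (2.29), glycolysis (0.25) and NF-kappaB genes (0.47) lost their calls. Regulatory (0.20), NF-kappaB (0.46) and glycolysis genes (0.21) lost theirs without both outlying libraries, NF-kappaB (0.90) and glycolysis genes (0.68) with RLE normalization, granulocyte (0.71) and glycolysis genes (0.62) without the filter on low counts, and glycolysis genes with the length offset (0.36). Granulocyte genes also lost the call without any 1 of propyzamide unstimulated replicates 2, 3 and 4 and propyzamide 24 h replicates 1, 2 and 4 (medians 0.99 to 1.69), glycolysis without propyzamide unstimulated replicates 1, 2 and 4 and propyzamide 24 h replicates 2, 3 and 4 (0.24 to 0.56), and mitochondrial genes without propyzamide unstimulated replicate 3 (-0.41).

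At 24 h with propyzamide edgeR called 3 genes, 2 higher and 1 lower, against 547 at an unadjusted p under 0.05. DESeq2 gave 55 higher and 16 lower, edgeR without the filter on low counts 25 and 9, and named protein-coding genes only without 2 outlying libraries 20 and 47. RLE normalization gave 7 higher and 1 lower, named protein-coding genes only 4 and 1, and the fit without 2 outlying libraries 13 and 26, each keeping all 3, while limma-voom called 1 and kept 0 and limma-trend called 2 and kept 1. Leaving out propyzamide unstimulated replicates 1, 2, 3 and 4 gave 0, 1, 0 and 0 called genes, and propyzamide 24 h replicates 1, 2, 3 and 4 gave 6, 0, 21 and 1. Lower among these were 1 without propyzamide unstimulated replicate 2, and 3, 13 and 1 without propyzamide 24 h replicates 1, 3 and 4. Zg16 was called in 4 of the 8 fits and Lag3 and Pml in 2, while the length offset and a fit of only the groups compared called 0 genes.

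Genes that moved after anti-CD3 did so in the same direction with vehicle and with propyzamide, with few exceptions. Of genes with an unadjusted p under 0.05 in both, 97 shared their direction at 3 h and 2 did not, and at 24 h these counts were 108 and 2. Of the called genes at 3 h, 4 were higher in both treatments, Ccl24, Gbp2, S100a9 and Serpina3g, where 0.0111 were expected by chance, and Itln1 was lower in both. At 24 h Lag3 was called higher in both, where 0.00632 were expected. The vehicle and propyzamide comparisons share no library, but at 24 h both set the same 2 i5 indexes against each other, so there a shared effect of the index cannot be told apart from a shared response. At 3 h only the propyzamide comparison differs in index.

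**Figure D4:**
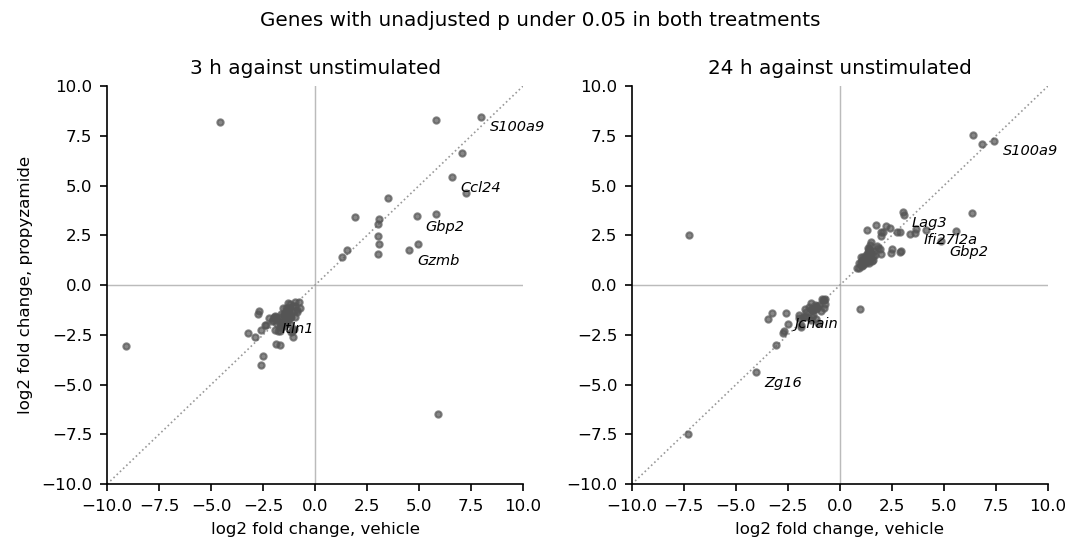
Each point is a gene with an unadjusted p under 0.05 in both treatments, with its log2 fold change against unstimulated for vehicle on the horizontal axis and for propyzamide on the vertical axis, at 3 h in the left panel and 24 h in the right. At 3 h 97 genes share their sign and 2 do not, and at 24 h 108 share it and 2 do not.

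Propyzamide against vehicle gave no called gene in the main edgeR fit at any stage. In unstimulated libraries the smallest p belonged to 4 predicted models, Gm43070, Gm48617, Gm49051 and Gm22690, and to Cnpy3, a chaperone of Toll-like receptors, with 17.1 ± 2.27 CPM with vehicle and 5.05 ± 2.72 with propyzamide (-1.83 ± 0.49, adjusted p = 0.692). Gm43070 had 137 counts with vehicle and 0 with propyzamide (adjusted p = 0.527). Ribosomal protein genes were higher as a list (73 of 79, median 0.40, adjusted p = 7.66e-08), as were glycolysis (10 of 10, 0.67, adjusted p = 0.00119) and intestinal epithelium genes (16 of 16, 0.85, adjusted p = 0.00244). For all 3 adjusted p = 0.897 with an estimated correlation, and 0 members passed adjusted over the list alone. The median over all named protein-coding genes was 0.16 and over the other tested genes -0.19. Without propyzamide unstimulated replicate 3, the library with the highest mitochondrial share of its group, the epithelial (median 0.17) and glycolysis calls (0.38) ended, and the glycolysis call also ended without vehicle unstimulated replicate 3 (0.50) and without the filter on low counts (0.41). edgeR called 0 genes, with 128 at an unadjusted p under 0.05, against 1 by DESeq2, 0 by limma-voom, 0 by limma-trend and 19 by edgeR without the filter on low counts.

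At 3 h after anti-CD3 Myl12b, a myosin regulatory light chain, had the smallest p of propyzamide against vehicle, with 2 counts against 33 (0.401 ± 0.801 and 11.5 ± 7.45 CPM, adjusted p = 0.581). Gm43305, Gm48313, Gm22690 and Mndal, an interferon-inducible DNA-binding protein, followed with adjusted p of 0.959 or more. No list passed, and the smallest adjusted p was 0.176, for mitochondrially encoded genes (2 of 16 positive, median -0.22). Tubulin and microtubule genes were at -0.46 (adjusted p = 0.839). edgeR called 0 genes, with 114 at an unadjusted p under 0.05, and DESeq2, limma-voom and limma-trend each called 0, against 11 by edgeR without the filter. Vehicle and propyzamide libraries carry different i5 indexes at this stage, so index and treatment cannot be told apart.

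At 24 h after anti-CD3 intestinal epithelium genes were higher with propyzamide as a list. All 16 were positive (median 2.67, also with Apoa4 and Phgr1 at their bounds, adjusted p = 4.80e-05), 12 of them adjusted over the list alone, with adjusted p = 0.601 with an estimated correlation. Lgals4 was at 2.05 ± 2.43 CPM with vehicle and 30.5 ± 52.2 with propyzamide (3.71 ± 1.0), and Fabp1 at 4.06 ± 1.18 (both adjusted p = 0.322). Without propyzamide 24 h replicate 3, the deepest library, the epithelial call ended (median 0.88), as it did without both outlying libraries (0.83). Ribosomal proteins (74 of 79, 0.41, adjusted p = 4.80e-05), glycolysis (10 of 10, 0.88, adjusted p = 0.00293), heat shock (8 of 8, 0.95, adjusted p = 0.00606), cell cycle (9 of 11, 0.84, adjusted p = 0.0197) and plasma cell genes (7 of 7, 0.81, adjusted p = 0.027, 2 adjusted over the list alone) were higher too. These gave, with an estimated correlation, adjusted p = 0.718 for ribosomal proteins, adjusted p = 0.621 for heat shock and adjusted p = 0.601 for the others. All named protein-coding genes had a median of 0.32 here and the other tested genes -0.43, a shift that the higher lists can hold too.

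Among single genes at 24 h, Prpsap1, a partner of phosphoribosyl pyrophosphate synthetase (chromosome 11, 116470845 to 116494202), had the smallest p, with 2.89 ± 1.36 CPM with vehicle and 18.5 ± 10.5 with propyzamide (2.82 ± 0.66, adjusted p = 0.322). Gm37951, Vmn2r58, Lgals4 and Gm21596 followed at the same adjusted p. edgeR called 0 genes, with 388 at an unadjusted p under 0.05, against 3 by DESeq2, 0 by limma-voom, 0 by limma-trend, 65 by edgeR without the filter and 1 without 2 outlying libraries. Without vehicle 24 h replicate 1 ribosomal proteins (0.21), heat shock (0.76), cell cycle (0.52) and plasma cell genes (0.59) lost their calls, and without propyzamide 24 h replicate 2 ribosomal proteins (0.17), heat shock (0.69) and cell cycle (0.64) did. Plasma cell genes also lost the call without vehicle 24 h replicate 3 (0.83) and propyzamide 24 h replicate 4 (0.94), and with named protein-coding genes only the plasma cell (0.57), cell cycle (0.57) and ribosomal calls (0.25) ended.

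Over the mean of the 3 stages propyzamide against vehicle gave 5 higher lists: ribosomal proteins (78 of 79, median 0.31, adjusted p = 1.03e-06), intestinal epithelium (16 of 16, 1.19, adjusted p = 3.17e-06, 11 adjusted over the list alone), glycolysis (10 of 10, 0.52, adjusted p = 0.00683), heat shock (8 of 8, 0.37, adjusted p = 0.00788, 1 adjusted over the list alone) and plasma cell genes (7 of 7, 0.49, adjusted p = 0.0109, 1 adjusted over the list alone). All 5 lost the call, with adjusted p = 0.746 with an estimated correlation. The median over all named protein-coding genes was 0.13 and over the other tested genes -0.22. Without both outlying libraries the epithelial median was 0.62. Glycolysis lost the call without vehicle unstimulated replicate 3 (0.41) or propyzamide 3 h replicate 1 (0.28), plasma cell genes without propyzamide 3 h replicate 1 (0.44) and with named protein-coding genes only (0.30), and heat shock without propyzamide 24 h replicate 2 (0.30). edgeR called 0 genes, with 326 at an unadjusted p under 0.05, against 1 by DESeq2, 0 by limma-voom, 0 by limma-trend and 42 by edgeR without the filter.

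Of the genes named in advance for propyzamide, only Nfkbia, the inhibitor of NF-kappaB, passed the filter on low counts. Its log2 fold change was 0.61 ± 0.57 unstimulated, -0.10 ± 0.57 at 3 h, -0.16 ± 0.56 at 24 h and 0.12 ± 0.32 over the 3 stages. Many counts of the others came from the deepest library, propyzamide 24 h replicate 3, so counts over the other 23 libraries follow in brackets. Ahr, the receptor for many environmental chemicals, had 164 counts over all 24 libraries (51), and its targets Cyp1a1, Cyp1b1, Ahrr and Tiparp had 11 (9), 159 (35), 347 (154) and 388 (130). Cebpb had 15 counts (12), Nfkb1 526 (146) and Rela 346 (113). The cytokines Ifng, Il17a, Il2 and Csf2 had 8 (2), 4 (0), 16 (14) and 5 (3) counts, against 402 (58) for Tnf, 73 (55) for Il22 and 255 (35) for Il10. Foxp3 had 92 (14), Il2ra 97 (31), Mki67 380 (79), Cd4 380 (84) and Cd8a 219 (65).

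The interaction of propyzamide and anti-CD3 called 0 genes in edgeR at 3 h (123 at an unadjusted p under 0.05) and 0 at 24 h (89), against 2 by DESeq2 at 24 h. At 3 h glycolysis (median -0.51, adjusted p = 0.0113), intestinal epithelium (-0.96, adjusted p = 0.0486) and ribosomal protein genes (-0.32, adjusted p = 3.21e-04) had lower responses with propyzamide, with 1 glycolysis gene passing adjusted over the list alone. At 24 h intestinal epithelium had a higher one (15 of 16 positive, 1.87, adjusted p = 0.0189). These calls ended, with adjusted p = 0.964 at 3 h and adjusted p = 0.879 at 24 h with an estimated correlation. Named protein-coding genes had a median of -0.23 at 3 h and 0.14 at 24 h, and the other tested genes 0.18 and -0.21. All 3 calls at 3 h ended without propyzamide unstimulated replicate 3 (-0.06, -0.36 and -0.12), vehicle unstimulated replicate 3 (-0.73, -0.92 and -0.20) or propyzamide 3 h replicate 3 (-0.36, -0.58 and 0.04), glycolysis also without vehicle 3 h replicate 4 (-0.56), and epithelium without any 1 of vehicle unstimulated replicates 1 (-0.72), 2 (-0.76) and 4 (-0.84), propyzamide unstimulated replicate 1 (-0.91), vehicle 3 h replicates 1 (-0.62) and 3 (-0.47) and propyzamide 3 h replicates 2 (-0.62) and 4 (-0.74). At 24 h the epithelial call ended without propyzamide 24 h replicate 3 (-0.41) or propyzamide unstimulated replicate 2 (2.02). Without both outlying libraries all 3 calls at 3 h (-0.40, -0.78 and -0.03) and the call at 24 h (-0.45) ended. At 3 h epithelium also lost the call with RLE normalization (-1.12), named protein-coding genes only (-0.60) or no filter on low counts (-0.53), and glycolysis with no filter (-0.21). Among the groups of the 3 h interaction only propyzamide 3 h carries the index TCTTACGC, so there index and interaction cannot be told apart.

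Lists tested but passing in no comparison were apoptosis, cholesterol synthesis, gut homing and residency, macrophage and monocyte, oxidative stress response, stroma, endothelium and erythroid, and unfolded protein and amino acid stress, with smallest adjusted p of 0.516, 0.117, 0.411, 0.369, 0.264, 0.0951 and 0.0718. The lists for cytotoxic lymphocytes, gamma-delta and innate-like T cells, T helper 2, T helper 17, aryl hydrocarbon receptor targets, C/EBP targets and T cell receptor variable segments had under 3 measured genes and were not tested. In every list that passed, median, mean and test had the same sign. T cell core genes had a median of -0.78 with propyzamide against vehicle unstimulated but a test direction upward (adjusted p = 0.792), and 0.79 at 3 h with propyzamide but a test direction downward (adjusted p = 0.716). Regulatory T cell genes had a median of -0.07 at 24 h with vehicle but a test direction upward (adjusted p = 0.0633).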

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

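The tests of the epithelial list, of the wrong label and of the scaling below were chosen only after the result was seen, as were the shares of satellite-like and named counts and the list scores. Measures of each library were searched for 1 sample far from the other 3 of its group, and 11 of 72 searches gave one, where chance gives about 1 in 20.

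Propyzamide 24 h replicate 3 stood far from the other 3 libraries of its group in 6 measures. It had 9812500 total counts, 42974 genes detected, 58.5% of counts in its top 50 genes, 40.2% in satellite-like models, 2944600 counts in named protein-coding genes and 30.01% of counts in them. Propyzamide unstimulated replicate 3 had a mitochondrial share of 5.49%, above the rest of its group. Vehicle 3 h replicate 1 had 0.327% of counts in ribosomal protein genes and 6.51% in named protein-coding genes, both above the rest of its group. Vehicle unstimulated replicate 2 had an intestinal epithelium score of 7.64, and propyzamide 3 h replicate 3 had a B cell score of 4.01, each apart from the others of its group.

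The response to anti-CD3 differed between propyzamide and vehicle for some lists by the test of the interaction with the preset correlation, and for none with an estimated correlation (adjusted p = 0.964 at 3 h and adjusted p = 0.879 at 24 h) or by fry. At 3 h the glycolysis list differed by -0.51, the intestinal epithelium list by -0.96 and the ribosomal protein list by -0.32 (median log2), and all 3 lost the call without propyzamide unstimulated replicate 3 (-0.06, -0.36 and -0.12), vehicle unstimulated replicate 3 (-0.73, -0.92 and -0.20) or propyzamide 3 h replicate 3 (-0.36, -0.58 and 0.04). At 24 h the intestinal epithelium list differed by 1.87, a call that ended without propyzamide 24 h replicate 3 (-0.41) or propyzamide unstimulated replicate 2 (2.02). In the 3 h interaction only the propyzamide 3 h group carries the i5 index TCTTACGC, so an effect of the index cannot be told apart from it.

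The higher epithelial list with propyzamide at 24 h rests on 1 library, and its call ended with an estimated correlation (adjusted p = 0.601). Without propyzamide 24 h replicate 3 its median went from 2.67 to 0.88 with an adjusted p of 0.0765, which is consistent with epithelial RNA in that library as the main source. Satellite-like counts in the scaling are argued against, since with named protein-coding genes only the list stayed higher (median 2.41, adjusted p = 1.93e-06 with the preset correlation, where other settings reached 0.0922). An unstimulated library under a wrong label is only weakly argued against. The interferon score of this library was 6.69 where the 8 unstimulated libraries lie between 4.57 and 5.2, while its epithelial score was 8.61. Genes without counts pull such a score down in shallow libraries, so the depth of this library can raise its scores. More epithelial tissue in the sample and an effect of propyzamide in 1 animal stay open, and the design has no second library that would separate them.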

How the results depend on the processing

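The settings restricted to named protein-coding genes, leaving out 2 outlying libraries, or doing both were chosen only after the result was seen. No paired analysis was possible because the labels give no replicate number, litter or batch. Over all settings, counts of called genes were within 1.5 times the reported count in 142 cases, larger in 49 and smaller in 39, and counts of called lists in 154, 10 and 44. Cases where both counts were 0 were taken as within 1.5 times. They make up most of the 142, so the tally says little about comparisons that had called genes. Single lists kept direction and call in 332 cases, lost the call in 86 and turned in 1, and named genes kept both in 623, lost the call in 488 and moved in 14. All 11 genes called at 3 h with vehicle were also called with RLE, without the filter, by DESeq2, with named protein-coding genes only, and without 2 outlying libraries, but the length offset kept 8, limma-voom 4, limma-trend 4 and a fit of only the groups compared the 5 it tested. All 16 called at 24 h with vehicle were also called by DESeq2, with named protein-coding genes only and without 2 outlying libraries, while 12 were without the filter, 11 with the length offset, the 10 it tested in a fit of only the groups compared, 9 by limma-voom, 5 with RLE and 0 by limma-trend. Named protein-coding genes of 23 libraries had 18119 to 161440 counts, which limits single genes. RLE moved the median of all genes from 0.00 to 0.13 for propyzamide unstimulated, from 0.09 to 0.30 at 24 h, from -0.13 to -0.26 for 3 h of anti-CD3 with propyzamide and from 0.03 to 0.23 for 24 h. The mean of the unstimulated and 24 h stages called 0 genes, as did the mean of 3.

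Where a setting changed a count, the cause was not tested unless named. Without the filter on low counts, which tests many more genes, edgeR called 19 genes for propyzamide against vehicle unstimulated, 11 at 3 h, 65 at 24 h and 42 over the stages. It called 57 for anti-CD3 at 3 h with vehicle, 64 at 24 h and 34 for 24 h against 3 h, then 65 and 34 at 3 h and 24 h with propyzamide, and 21 and 20 for the interactions. List calls were 13 at 24 h and 14 over the stages for propyzamide against vehicle, and 1 and 2 for the interactions.

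DESeq2 called 1, 3 and 1 genes for propyzamide against vehicle unstimulated, at 24 h and over the stages, and 2 for the interaction at 24 h. For anti-CD3 it called 34 at 3 h and 34 at 24 h with vehicle, 79 for 24 h against 3 h, and 78 and 71 with propyzamide. A fit of only the groups compared called 1 gene for propyzamide at 24 h, 26 at 3 h, 51 at 24 h and 56 for 24 h against 3 h with vehicle, and 0 and 0 with propyzamide, with fewer libraries to estimate the spread. Limma-voom called 18 at 3 h with vehicle, 6 for 24 h against 3 h, and 7 and 1 with propyzamide. Limma-trend on log2(TPM + 1) called 7 at 3 h and 0 at 24 h with vehicle and 5 at 3 h with propyzamide. RLE called 5 at 24 h with vehicle, 2 for 24 h against 3 h, and 53 and 8 with propyzamide, and the transcript length offset called 13 and 0 with propyzamide.

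With named protein-coding genes only, edgeR called 21 at 3 h, 34 at 24 h and 15 for 24 h against 3 h with vehicle, and 15 and 5 with propyzamide. Lists called were 3 for propyzamide at 24 h, 3, 5 and 6 for the vehicle comparisons, and 6 and 6 with propyzamide; T cell receptor and immunoglobulin constant genes are absent from this setting, so these lists had fewer members. Without 2 outlying libraries edgeR called 1 gene for propyzamide at 24 h, 31, 43 and 40 for the vehicle comparisons and 39 at 24 h with propyzamide. Lists called were 2 for propyzamide at 3 h, 6 for 3 h of anti-CD3 with propyzamide, and 0 and 0 for the interactions. With both changes genes called were 28, 77 and 42 for the vehicle comparisons and 67 at 24 h with propyzamide. Lists called were 1 at 3 h and 3 at 24 h for propyzamide against vehicle, 7 at 24 h and 7 for 24 h against 3 h with vehicle, 5 and 6 with propyzamide, and 0 for the interaction at 3 h. Ribosomal proteins in that interaction turned from -0.32 to 0.10 with both changes, and the cause was not tested.

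With an estimated correlation 0 lists passed for propyzamide against vehicle unstimulated (3 with the preset), at 24 h (6) and over the stages (5), 0 at 3 h with vehicle (7), 1 at 24 h (11, the interferon list), 0 for 24 h against 3 h (11), 0 and 0 with propyzamide (12 and 14), and 0 for both interactions (3 and 1). Fry passed 0 for propyzamide against vehicle at each of these stages, 0 at 3 h with vehicle, 7 at 24 h, 2 for 24 h against 3 h, 6 and 6 with propyzamide, and 0 for the interactions.

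Leaving out each library in turn gave 4 to 10 called genes at 3 h with vehicle, 1 to 9 at 24 h, 0 to 2 for 24 h against 3 h, 0 to 33 at 3 h and 0 to 21 at 24 h with propyzamide, and 0 to 1 for each interaction. Propyzamide against vehicle had 0 called genes in all of these fits. Since the filter was repeated and kept more genes in each, a changed count may not be due to the left-out library alone. Lists called were 1 to 4 for propyzamide against vehicle unstimulated, 0 to 2 at 3 h, 2 to 8 at 24 h and 3 to 5 over the stages, 6 to 13 at 3 h with vehicle, and 0 to 3 and 0 to 1 for the interactions.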

Other observations

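The gene families, the tests of the propyzamide comparisons, of the interferon and epithelial lists and of the shared response, and the splits compared by genes at an unadjusted p under 0.05, were chosen only after the result was seen, while the splits compared by called genes were set before. The 3 gene families were picked because of their values and were not tested as lists, so the signs below describe these libraries and test no pattern. Of the interferon-inducible GTPases, which attack the vacuoles of intracellular pathogens and include the called gene Gbp2, all 9 measured members (Gbp2, Gbp4, Gbp6, Ifi47, Igtp, Iigp1, Irgm1, Tgtp1, Tgtp2) were positive with vehicle at 3 h (median 1.51) and 24 h (1.93) and with propyzamide at 3 h (2.46) and 24 h (2.62). With RLE, the length offset and DESeq2 8 of 9 were positive at 3 h with vehicle, and on TPM 7 of 9. Of the genes of MHC class I presentation, which load peptides for CD8 T cells, all 14 (among them B2m, H2-K1, H2-D1, Psmb8, Psmb9, Tap1 and Tapbp) were positive at 24 h with vehicle (median 1.36, 11 with an unadjusted p under 0.05) and with propyzamide (1.46, 12). At 3 h 6 of 14 were positive with vehicle (-0.06, and 0.04 with the length offset) and 5 of 14 with propyzamide (-0.19, and 0.03 with named protein-coding genes only). With vehicle the class I genes were higher at 24 h than at 3 h (14 of 14, 1.43, 9 with an unadjusted p under 0.05), while 6 of the 9 GTPases were (0.21). Paralogs in both families share reads, so single members are uncertain.

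Of 22 alpha-defensin genes, made by Paneth cells and too alike to count as independent evidence, 18 were negative at 3 h (median -1.46) and 20 at 24 h (-1.20) with vehicle, and 21 at 3 h (-1.66) and 21 at 24 h (-1.21) with propyzamide.

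In the main edgeR fit no gene passed for propyzamide at any stage, and 3 technical explanations were weighed. Depth too low for any call is argued against by the 11 genes called at 3 h with vehicle, with as many libraries and totals in the same range. Smaller changes than those can be missed, so depth may still hide changes. In simulation 4.14% to 8.74% of 2-fold changes in genes that the filter kept were found at a single stage. Of the panel all genes but Nfkbia were too low to be tested. With named protein-coding genes only, 0 genes were called over these comparisons, so taking satellite-like counts out of the scaling brought no call for propyzamide. The same setting raised calls with vehicle from 11 to 21 at 3 h, from 16 to 34 at 24 h and from 0 to 15 for 24 h against 3 h. The genes it leaves out may therefore have cost calls, and a further 0 does not exclude such a cost for propyzamide. Without the 2 outlying libraries 1 gene was called over these comparisons, while calls with vehicle rose from 11 to 31 at 3 h and from 16 to 43 at 24 h. The outlying libraries may therefore have widened the spread, but leaving them out, which also shrinks their own groups, brought only that 1 call for propyzamide. With 0 genes called in the real split, 35 of 35 splits for each stage (highest other 1, 2 and 1) and 100 of 100 for the mean of the stages (3) and the interactions (1 and 1) reach it whatever the data, so splits by called genes decide nothing there. By genes at an unadjusted p under 0.05 chance cannot be excluded for propyzamide unstimulated (128 genes, reached by 8 of 35 splits, highest other 417), at 3 h (114, 30 of 35, 313), at 24 h (388, 3 of 35, 699), over the mean of the stages (326, 5 of 100, 601) or for the interactions at 3 h (123, 33 of 100, 544) and 24 h (89, 83 of 100, 456). A small effect of propyzamide, or none, stays open.

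At 24 h with vehicle the interferon list was higher and the epithelial list lower. A lower share of epithelial RNA that raises every other list alike is argued against, since the interferon score rose over the B cell score by 1.1 (-1.42 ± 0.63 against -2.52 ± 0.6, exact permutation p = 0.0286, the smallest possible). Satellite-like counts in the scaling are argued against, since with named protein-coding genes only both lists passed with the preset correlation (medians 2.25 and -3.15, larger adjusted p = 6.13e-13). With an estimated correlation in the main fit the interferon list passed and the epithelial list did not. The i5 index as the whole cause is argued against, since the 3 h groups, which differ in index, differ by 0.0405 in the interferon list (adjusted p = 0.849) against 1.57 at 24 h, and by -0.11 in the epithelial list against -2.91, unless propyzamide offset the index in both. An interferon response to anti-CD3 with a loss of epithelial transcripts may account for the pattern, a hypothesis found and tested on the same data.

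The anti-CD3 comparisons were set against other splits of the same libraries. By called genes, the real split alone reached its count at 3 h with vehicle (1 of 35 splits, 11 genes, highest other 2), at 24 h with vehicle (1 of 35, 16 genes, highest other 0) and at 3 h with propyzamide (1 of 35, 27 genes, highest other 1). A share of 1 in 35 is the smallest possible and was not adjusted over the comparisons, so it argues against chance without excluding it. Chance is not argued against for 24 h with propyzamide, where 3 of 35 splits gave at least the real 3 genes. There 1 split gave 105 genes, and it put propyzamide 24 h replicate 1 with unstimulated replicates 1, 2 and 4. These libraries had 4.65% to 7.26% of their counts in named protein-coding genes, and the others of the 2 groups 7.99% to 30.01%. For ribosomal protein genes the shares were 0.16% to 0.50% and 0.58% to 1.69%. This split thus follows the RNA content of the libraries, and whether that gives the 105 genes was not tested. For 24 h against 3 h with vehicle the real count of 0 is reached by every split (highest other 1) and decides nothing. By genes at an unadjusted p under 0.05, the real split alone reached its count for 24 h against 3 h with vehicle (462 genes, 1 of 35, highest other 386) and at 3 h with propyzamide (508, 1 of 35, 468). It did not at 3 h with vehicle (237, 2 of 35, 264), at 24 h with vehicle (272, 2 of 35, 274) or at 24 h with propyzamide (547, 4 of 35, 804). For genes that moved in both treatments, 97 shared their direction at 3 h, a count reached by 1 of 70 ordered splits of the propyzamide libraries (highest other 52), and 108 at 24 h, reached by 1 of 70 (highest other 55). At 24 h both treatments set the same 2 i5 indexes against each other, so there the agreement cannot be told apart from an effect of the index.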
